A study of Homo sapiens with 3 samples.

How the data were processed

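RNA from 3 stably transfected lines of A549, a human lung adenocarcinoma cell line, was measured on 1 long non-coding RNA array each. The lines carried a control shRNA, an shRNA against Caspase-8 or an shRNA against c-Src. Total RNA was extracted with TRIzol, amplified linearly and labelled with Cy3 as 1-colour cDNA, per the labels' protocols. Agilent Feature Extraction 10.10 was named per the submitters' processing notes. The deposited value of each probe was an intensity on a linear scale, judged from the values, which were positive and had different quartiles on each array. The background correction and any normalization behind these intensities are not given in the sources used here. Each array's table broke off inside its last line, so 1 line per array was left out, 3 in all, and the tables hold part of the probes of each array. Probes beyond the end of a table were not analysed here.

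The control array listed 13881 probes, the Caspase-8 shRNA array 11004 and the c-Src shRNA array 13468, besides 54, 53 and 54 control features of the platform. All 11004 probes of the Caspase-8 shRNA array were listed on all 3 arrays. Of the probes on the control array, 7808 had identifiers that began with RNA and 6073 had identifiers that began with CB. The former carry the name of a database, a transcript or an RNA class, and the latter carry only a number. The tables do not pair probes with gene symbols. No probe name equalled a symbol in the gene tables used here, and 0 of the 587 Ensembl transcript identifiers were found in them. The 33 gene lists fixed beforehand, with 1032 genes, therefore had 0 genes measured by a named probe. Of these genes, only GAPDH and PGK1 had control features of the platform. CASP8 and SRC, the targets of the knockdowns, were not analysed here for the same reason, so the labels were not checked against them.

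Intensities were transformed to log2, and the 75th percentile of each array over the 11004 shared probes was subtracted. No pseudocount, floor or filter on dim probes was used in the main counts. With 1 array per group there were no replicates, and no p-value was calculated for the difference of a probe or family. A probe was counted as higher or lower when its scaled signal differed at least 2-fold. An exact binomial test compared the probes 4-fold lower and 4-fold higher in both knockdowns, 5 each way, and showed no excess of lower ones. The number of arrays limits the precision, and no interval was given. The design assumed that values might be normalized already, and the scaling for scanner output, written down at the same time, was used instead. The signal of the dark corner, a platform feature that does not bind the sample, served as the background level of each array. A fold against an array where the probe was not above the dark corner was given as a lower bound against that level.

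The rule for named features took the RNA identifiers whose mean log2 signal was at or above the median of the shared probes, which left 2523. It named the 10 highest and the 10 lowest for each knockdown against control. It also named the 10 highest and 10 lowest in both knockdowns, ranked by the smaller of the absolute differences. The 5 largest differences each way were named for c-Src shRNA against Caspase-8 shRNA. At most 2 identifiers each way are printed per comparison where the identifier carries no RNA name, and the others are given as ranges. Up to 4 members of an identifier family were listed, those with the largest mean difference. The groups, comparisons, 2-fold size, naming rule and most of the other settings listed below were fixed before the data were examined. The families, the CB identifiers singled out, the use of the dark corner and the spike-in analyses were chosen after the values had been seen.

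Identifier families were compared over probes above the dark corner on all 3 arrays. The median difference of a family with at least 5 such probes was placed among 10000 random sets of the same size, matched on mean signal in 20 bins. This percentile describes these arrays only. Of the E1A spike-in probes, 8 were above the dark corner on all 3 arrays and 2 dimmer ones were left out. For the 8, the standard deviation of the differences was placed among 2000 sets of listed probes, each drawn from the 200 probes nearest in mean signal to each spike-in. Arrays without real differences that shared 1 control array were simulated 100 times from the observed spread.

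The calling procedure was tested on simulated data with 200 changed probes among the 6883 above the dark corner on all 3 arrays, with the whole observed spread taken as error. For the Caspase-8 comparison, 46.5% of 2-fold, 83.5% of 4-fold and 98.0% of 8-fold changes were recovered. Between 32.3% and 33.2% of unchanged probes were then counted as well. For the c-Src comparison, 48.0%, 96.5% and 100.0% were recovered and 7.21% to 7.68% of unchanged probes were counted.

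The settings chosen beforehand to vary the processing were quantile normalization, median centring, cyclic loess, 2 filters on mean signal, a pseudocount of 16, thresholds of 1.5-fold and 4-fold, and a restriction to probes listed on all 3 arrays. A restriction to probes above the dark corner, scaling on the spike-ins and a common floor were added after seeing the data. Spike-in scaling subtracted each array's median log2 signal over the 8 E1A probes, which is not the median of their differences. Taking off those medians, 1.19 for Caspase-8 and 0.30 for c-Src, would lower the Caspase-8 differences further and the c-Src differences less. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3 for quantile and cyclic loess normalization (span 0.4, 3 iterations).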

Results

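Long non-coding RNA was profiled in A549 cells that carried a control shRNA, an shRNA against Caspase-8, the initiator caspase of death receptor signalling, or an shRNA against c-Src, a tyrosine kinase of adhesion signalling. The labels call the control line mesenchymal-like and both knockdown lines epithelial-like. The stated aim was to find long non-coding RNAs needed for drug resistance in the mesenchymal-like cells. Each line had 1 array, so there were no replicates, and no difference below could be set against a replicate spread. Whether the targeted transcripts were reduced was not analysed here, because the probe identifiers are not paired with gene symbols.

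The median signal over the 11004 shared probes was 115 on the control array, 53.4 on the Caspase-8 shRNA array and 89.5 on the c-Src shRNA array. The lowest listed signal was 5.12, 19.8 and 5.26, and the dark corner read 6.68, 27.6 and 6.74, in the same order. Of the shared probes, 85.3%, 65.3% and 81.6% were above the dark corner, and 6883 were above it on all 3 arrays. Across probes, which are not independent replicates, the control array correlated with the c-Src shRNA array at a Spearman rho of 0.976 and with the Caspase-8 shRNA array at 0.902. The Caspase-8 and c-Src shRNA arrays correlated at 0.902. GAPDH, measured by a platform feature at its 5' end, had signals of 87808, 93881 and 85190 before scaling. The PGK1 feature of the same kind had signals of 7658, 6207 and 7082. Scaled to the 75th percentile, these 5' features of the glycolytic genes were higher, by 1.11 and 0.71 on the log2 scale in the Caspase-8 shRNA array. In the c-Src shRNA array they were higher by 0.42 and 0.35, but that of PGK1 was not higher in either with spike-in scaling. When the arrays were scaled on the spike-in probes, GAPDH differed by 0.24 and 0.05 and PGK1 by -0.16 and -0.02 in the Caspase-8 and c-Src shRNA arrays. The sign for GAPDH in the Caspase-8 shRNA array depends on how the spike-ins are used, as 1.11 lay below their median difference of 1.19. Another, brighter PGK1 feature read 31564 on the control array and 26314 on the c-Src shRNA array, a scaled difference of 0.20. It was not listed on the Caspase-8 shRNA array.

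In the Caspase-8 shRNA line, the RNA named RefSeq_253_4942 was 64.2-fold lower than in the control line, with signals of 48.3 and 6249. ENCODE_2283_423 was 19.1-fold lower, with signals of 109 and 4209. The highest of the named features was H-InvDB_853_486, at 3116 against 694, which was 9.04-fold after scaling. XLOC_012765 followed at 889 against 207, an 8.64-fold difference. On the log2 scale these 4 differences were -6.01, -4.25, 3.18 and 3.11, and with spike-in scaling they were -6.87, -5.12, 2.31 and 2.24. The RNA component of RNase MRP, a ribonucleoprotein that takes part in ribosomal RNA processing, had signals of 19753 and 11509 and a difference of 1.79 on the log2 scale. With spike-in scaling this difference was 0.92, under 2-fold. Of the 10 lowest named features, 7 were above the dark corner on both arrays and ranged from -6.01 to -3.08 on the log2 scale. The other 3 were not above it on the Caspase-8 shRNA array and were at least 7.57-fold to at least 8.85-fold lower. The 10 highest ranged from 2.43 to 3.18. With spike-in scaling the 7 ranged from -6.87 to -3.94 and the 10 highest from 1.56 to 2.31.

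Groups of RNAs that share an identifier type, as the tables print it, were set against equally bright probes. In this comparison the 8 E1A probes above the dark corner on all 3 arrays, which on this platform measure RNA added to each sample, had a median difference of 1.19, with 2 dimmer E1A probes left out, against 0.33 for probes above the dark corner on both arrays. The 32 UCRs features above the dark corner on all 3 arrays had a median difference of -0.40, at the 0.080th percentile of random sets of equal brightness, whose median was 0.31. This median stayed below 0 under each of the scalings tried, and 10 of the 32 were at least 2-fold lower while 6 were at least 2-fold higher. With spike-in scaling these numbers were 18 and 0. UCRs_292_230 was 3.99-fold lower, UCRs_269_236 differed by -1.79 on the log2 scale and UCRs_267_237 by 1.71. With spike-in scaling these 3 differed by -2.86, -2.66 and 0.84. The 26 EvoFold features had a median of -0.10, at the 0.13th percentile, and the 67 asoverlaps features a median of -0.11, at the 0.55th percentile. Both medians were below 0 under each scaling, but only just with median centring, at -0.01 and -0.02. Of the EvoFold features 6 were at least 2-fold higher and 7 at least 2-fold lower, and of the asoverlaps features 12 and 11. The 8 features from lncRNAdb, a database of long non-coding RNAs with a known function, had a median of 0.90, at the 93.6th percentile, and of 0.04 with spike-in scaling. Of these 8, 3 were at least 2-fold higher and 1 at least 2-fold lower, or 1 and 2 with spike-in scaling. Among the higher ones, lncRNAdb_15_2956 had signals of 214 and 77.1 (2.48, or 1.62 with spike-in scaling), and lncRNAdb_66_332 had 181873 and 105653 (1.79, or 0.93 with spike-in scaling). The 291 H-InvDB features had a median of 0.58, at the 99.2nd percentile, and it was -0.29 when the arrays were scaled on the spike-ins. The 306 imsncRNA features (0.38) and the 365 RNAz features (0.53) were both at the 97.9th percentile, and with spike-in scaling, which moves the random sets alike and leaves the percentiles as they were, their medians were -0.49 and -0.34. Of 12 non-coding RNAs of the HOX clusters, which hold developmental transcription factor genes, 2 were at least 2-fold higher and 0 at least 2-fold lower. These were int-HOXC12-32, at 1726 against 1194 (1.54), and hox-HOXB8-86, at 58.0 against 44.0 (1.41). With spike-in scaling 0 HOX features were at least 2-fold higher and 5 at least 2-fold lower. The HOX median of 0.20 was at the 27.3rd percentile and turned to -0.67 with spike-in scaling. The 8 snRNA features had a median of 0.48, at the 46.7th percentile, which turned to -0.06 under cyclic loess and -0.39 with spike-in scaling.

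**Figure D1:**
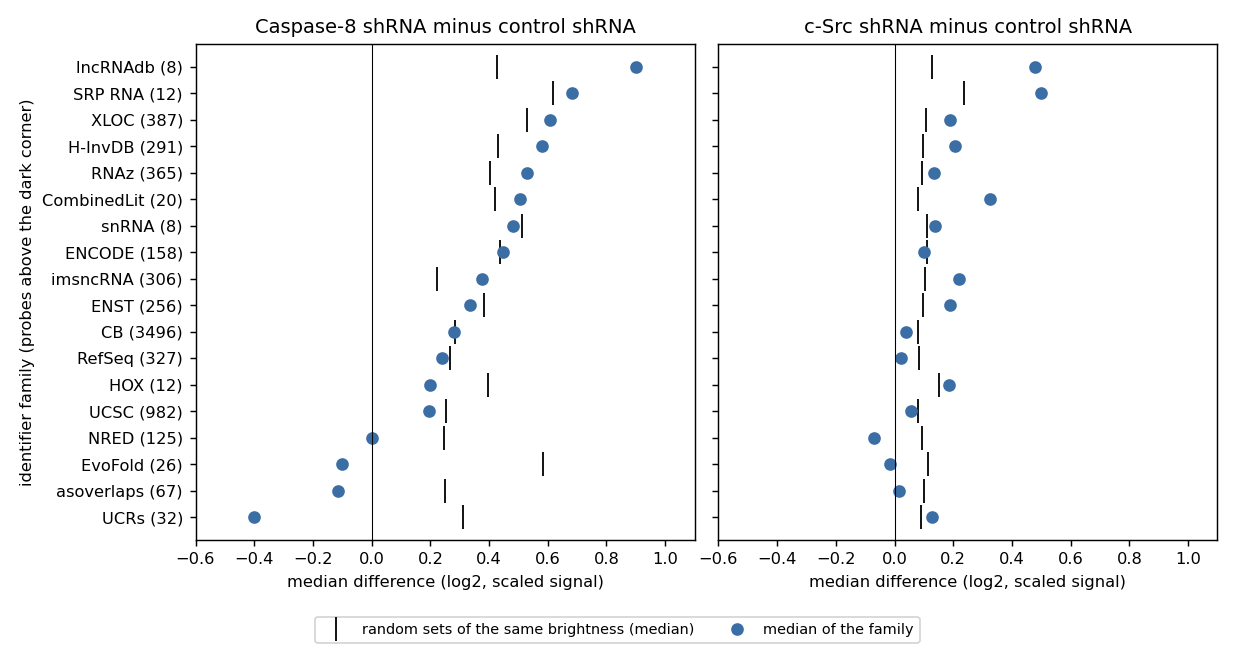
Median log2 difference of scaled signal between each knockdown array and the control array (horizontal axis) for 18 identifier families (vertical axis, with the number of probes above the dark corner), as points, with the median of random sets of the same brightness as bars. On the Caspase-8 side the UCRs median of -0.40 lies left of its bar at 0.31, and on the c-Src side the SRP RNA median of 0.50 lies right of its bar at 0.24. Spike-in scaling moves points and bars alike, so it turns the sign of 14 of the 18 medians in each panel but not their side of the bars.

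Over all 11004 shared probes, 4551 were at least 2-fold higher and 986 at least 2-fold lower in the Caspase-8 shRNA array. The median difference was 0.71, so most of the array lay above the control after scaling. Of the higher probes, 1421 were above the dark corner on neither array and 1313 only on the control array, so the Caspase-8 shRNA array read them at or below its own dark corner. Among the 6993 probes above the dark corner on both arrays, 1625 were higher and 783 lower, with a median of 0.33. They comprised 892 higher and 374 lower among 3463 RNA identifiers, and 733 and 409 among 3530 CB identifiers. On the scaled log2 scale the dark corner lay at -4.09 in the Caspase-8 shRNA array and at -7.15 in the control array. A probe just above both could therefore read higher with little signal. After cyclic loess, 923 of the 1625 higher and 725 of the 783 lower probes were still 2-fold apart. With the common floor, 1088 of the shared probes were higher and 946 lower. In the main counts over all 11004 probes the higher share was 82.2%. It was 49.5% after quantile normalization, 48.2% after cyclic loess and 49.7% with spike-in scaling. The first 2 methods centre the differences and the third moves every probe alike, taking the median from 0.71 to -0.15, so these shares followed from where each scaling set 0 and did not test for a predominant direction.

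**Figure D2:**
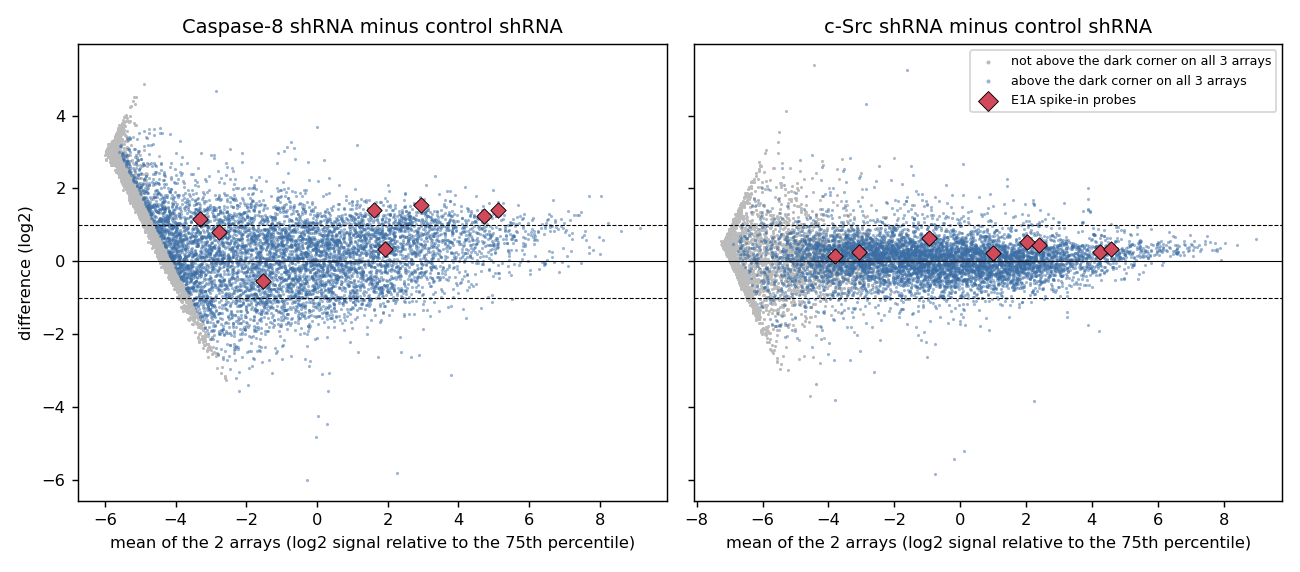
Log2 difference of scaled signal (vertical axis) against the mean of the arrays compared (horizontal axis, log2 relative to the 75th percentile) for each shared probe, with probes above the dark corner on all 3 arrays, other probes and the 8 E1A spike-in probes marked apart, and dashed lines at 2-fold. The Caspase-8 comparison spreads widely, with a median of 0.71 over 11004 probes, and the c-Src comparison is narrower, with a median of 0.17 over those it lists.

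In the c-Src shRNA line, ENCODE_2283_423 was 57.2-fold lower than in the control line, with signals of 53.3 and 4209, and RefSeq_253_4942 was 37.2-fold lower, at 122 against 6249. UCSC_11223_440 was 7.12-fold higher, at 461 against 89.3, and ENST00000475886 was 6.31-fold higher, at 1818 against 398. The lncRNAdb feature lncRNAdb_54_651 had signals of 16490 and 8604, a difference of 1.40 on the log2 scale. The 10 lowest named features ranged from -5.84 to -1.74, and the 10 highest from 1.69 to 2.83. One feature without an RNA name, CB_031281, was singled out after its values had been seen, with a signal of 1377 against 50.3, which was 37.8-fold higher. It was picked as the CB feature highest in both knockdowns. In the Caspase-8 shRNA array it read 114 and was 4.57-fold higher, or 1.33 on the log2 scale with spike-in scaling.

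The 8 E1A probes had a median difference of 0.30 in this comparison. SRP RNA, the RNA of the signal recognition particle that guides secretory proteins to the endoplasmic reticulum, had a positive difference between the c-Src shRNA and control arrays for 12 of 12 features, but for 9 with spike-in scaling, and 1 of the 12 was at least 2-fold higher. The median difference was 0.50, at the 99.8th percentile of sets of equal brightness, and it stayed above 0 under each of the scalings tried, at 0.13 with spike-in scaling. The 12 features carry the name of 1 RNA, so they may repeat 1 measurement, while the random sets were drawn from all probes. Neither the 12 of 12 nor the percentile counts independent evidence. SRP_RNA_119_290 had signals of 3392 and 1972 (1.25, or 0.88 with spike-in scaling), and SRP_RNA_149_280 had 28942 and 22184 (0.85). The 8 lncRNAdb features had a median of 0.48, at the 99.2nd percentile, and 0.11 with spike-in scaling. The 291 H-InvDB features (0.21) and the 306 imsncRNA features (0.22) were at the 99.99th percentile and above all 10000 random sets, and with spike-in scaling, which again leaves the percentiles as they were, their medians were -0.17 and -0.15. Of the H-InvDB features 9 were at least 2-fold higher and 6 at least 2-fold lower, and of the imsncRNA features 0 and 1. The 256 ENST and 387 XLOC features, both with a median of 0.19, were at the 99.8th percentile, and each median was -0.18 with spike-in scaling. The CB features, which made up 3496 of the 6883 probes that the random sets were drawn from, had a median of 0.04, below all 10000 random sets, and it was below 0 under the other scalings tried. The high ranks of the RNA families are therefore in part ranks against CB features. The 125 NRED features had a median of -0.07, at the 0.13th percentile, and this median was below 0 under each scaling. Of the 12 HOX features, 0 were at least 2-fold apart from control in either direction, and 1 was at least 2-fold lower with spike-in scaling. Their median of 0.19 was at the 59.6th percentile and turned to -0.18 with spike-in scaling. The 32 UCRs features, at the 66.1st percentile with a median of 0.13, were not among the lowest families here, and their median was -0.24 with spike-in scaling. The difference between the comparisons was not tested. The 8 snRNA features had a median of 0.14, at the 56.9th percentile, which turned to -0.23 with spike-in scaling and to just below 0 under quantile normalization.

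Over the 13468 probes listed on both arrays, 737 were at least 2-fold higher and 541 at least 2-fold lower in the c-Src shRNA array, with a median difference of 0.17. Among the 10644 above the dark corner on both, 542 were higher and 384 lower. RNA identifiers made up 293 of those higher and 208 of those lower, and CB identifiers 249 and 176. The higher share was 57.7%, or 58.5% over the 11004 shared probes, where it was 46.2% with median centring. It was 19.7% over the 13468 with spike-in scaling. Both alternatives move every probe alike, and spike-in scaling took the median to -0.20, so these shares followed from where 0 was set and did not test a direction.

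RNAs that were lower in both epithelial-like lines than in the mesenchymal-like control line bear on the stated aim. Among features with an RNA identifier, RefSeq_253_4942 and ENCODE_2283_423 had the largest shared differences, at -6.01 and -5.22 for the former and -4.25 and -5.84 for the latter in the Caspase-8 and c-Src shRNA arrays. Among features higher in both, ENST00000445836 had signals of 264, 366 and 599 in the control, Caspase-8 and c-Src shRNA arrays, or 1.48 and 1.65 above control after scaling, but its Caspase-8 difference was 0.61 with spike-in scaling. XLOC_012765 had 207, 889 and 404, or 3.11 and 1.43. SRP_RNA_119_290 was also among the 10 highest in both, by 1.32 and 1.25, but by 0.46 and 0.88 with spike-in scaling. CB_029506, singled out after its values had been seen, was 22.0-fold and 42.9-fold lower, at 122 and 91.6 against 5422. CB_031281, singled out in the same way, was 4.57-fold and 37.8-fold higher. The 10 lowest shared features ranged from -6.01 to -1.18 in the Caspase-8 comparison and from -5.84 to -1.13 in the c-Src comparison.

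Of the 6883 probes above the dark corner on all 3 arrays, 33 were at least 2-fold lower and 95 at least 2-fold higher in both knockdown arrays. Unchanged arrays sharing 1 control array gave 88.2 lower and 88.0 higher on average in simulation, and independent lists of the same sizes would share 22.2 and 54.7. The simulation gave near equal numbers each way, while the observed differences had medians of 0.31 for Caspase-8 and 0.09 for c-Src. The 33 against 88.2 therefore depends on where the scaling set 0 and does not show fewer shared falls than in unchanged arrays. Part of any overlap may come from the shared control array, which could not be split. The covariance of the differences was 0.125 against 0.159 in the simulation, and their correlation across probes was 0.22 (Pearson) and 0.19 (Spearman) against a simulated Pearson value of 0.31. At the 4-fold size, 5 probes were lower in both and 5 higher, and the simulation gave 5.88 lower on average. After cyclic loess, the same 5 probes were still 4-fold lower in both, and 1 was 4-fold higher. Over all 11004 shared probes, 406 were higher and 46 lower in both, but 62 and 130 after quantile normalization.

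The knockdown lines also differed from each other. XLOC_012621 and XLOC_003100 were 16.2-fold and 12.7-fold higher in the c-Src than in the Caspase-8 shRNA array, with signals of 695 against 29.4 and 3150 against 170. The 29.4 lay just above the dark corner of 27.6, and with a pseudocount of 16 the difference of XLOC_012621 was 3.44 in place of 4.02 on the log2 scale. On the control array they read 706 and 4048, close to the c-Src values before scaling. ENCODE_456_1286 was 21.0-fold lower in the c-Src shRNA array, at 38.9 against 560 and 443 on the control array. RefSeq_747_3250 was 7.83-fold lower, at 57.7 against 310 and 276. A ribosomal RNA feature, rRNA_31_484, read 586 against 127, with 537 on the control array, a difference of 1.66 on the log2 scale. The other, much brighter, ribosomal RNA feature above the dark corner, rRNA_5_1868, read 115769 against 92026, a scaled difference of -0.21.

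Over the 11004 shared probes, 1085 were at least 2-fold higher and 4520 at least 2-fold lower in the c-Src than in the Caspase-8 shRNA array, with a median of -0.65. Among the 6916 above the dark corner on both arrays, the counts were 860 and 1541, with a median of -0.22. After cyclic loess, 746 of the 860 and 1009 of the 1541 were still 2-fold apart. In the main counts over the 11004 probes the higher share was 19.4%. It was 48.6% after quantile normalization, 48.6% after cyclic loess and 38.2% with spike-in scaling, which took the median to -0.16. These shares again followed from where each scaling set 0 and did not test a direction.

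**Figure D3:**
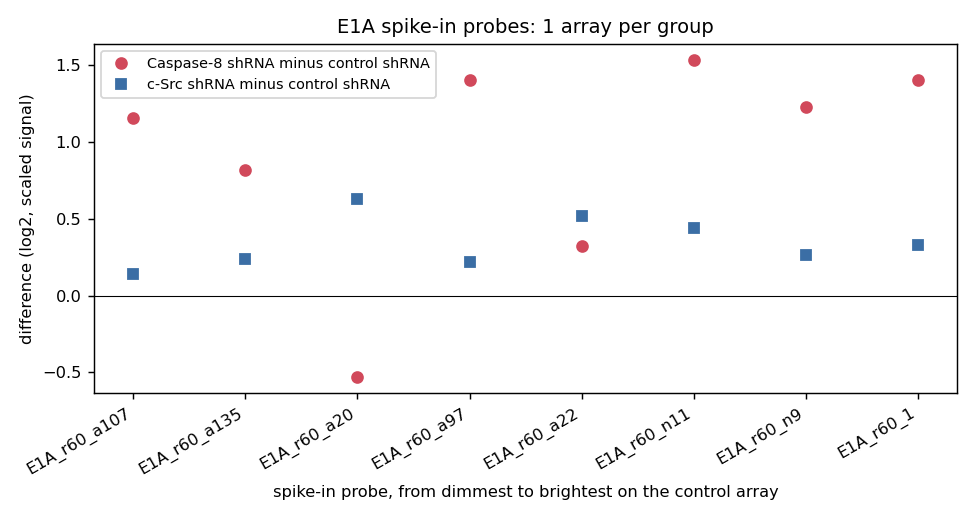
Log2 difference of scaled signal between each knockdown array and the control array (vertical axis) for 8 E1A spike-in probes (horizontal axis, from dimmest to brightest on the control array), with 1 point per probe and comparison. The Caspase-8 values run from -0.53 to 1.54 and the c-Src values from 0.14 to 0.63.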

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

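The spike-in test and the test on bright probes were chosen only after the Caspase-8 result was seen, and the loess test was chosen before.

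The E1A probes measure RNA added to each sample and were outside the probe counts and named features above. They drew attention because their median scaled signal was above control. Their median difference between the Caspase-8 shRNA and control arrays was 1.19 after scaling, over the 8 probes above the dark corner on all 3 arrays and without 2 dimmer ones, against 0.30 between the c-Src shRNA and control arrays. Before scaling these medians were 0.18 and -0.17, while the probes above the dark corner on all 3 arrays had medians of -0.70 and -0.38. The platform feature ERCC-00012_90 drew attention as well, with a signal of 522 on the Caspase-8 shRNA array against 278 on the control array and 267 on the c-Src shRNA array. Another such feature, ERCC-00043_129, was lower than control before scaling, at 242 and 232 against 289.

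The Caspase-8 shRNA array stood apart from the other arrays. Its higher background alone was argued against by 3383 probes at least 10 times above the dark corner on all 3 arrays. Of these, 25.9% were at least 2-fold apart from control, against 4.26% for c-Src, a ratio of 6.08. They were 669 higher and 207 lower for Caspase-8, and 70 and 74 for c-Src. The dark corner of 27.6 on the Caspase-8 shRNA array, against 6.68 on the control array, made this filter favour probes that read high on the former. The size of the ratio therefore depends in part on the filter and on where the scaling set 0. A trend with brightness left by the scaling was argued against as the whole cause, since after cyclic loess 1823 of the 6883 probes above the dark corner on all 3 arrays were at least 2-fold apart from control, against 438 for c-Src, a ratio of 4.16. The labelling or hybridisation of that array stays open, because the spike-in differences had a standard deviation of 0.70, at the 32.5th percentile of equally bright probes. Leaving out 1 probe at a time gave values up to 0.76. The lowest was 0.42, at the 6.30th percentile, without E1A_r60_a20, which was picked because leaving it out lowered the value most. For c-Src the spike-in standard deviation was 0.17, at the 1.05th percentile, and without the same probe it was 0.13, at the 0.25th percentile. An effect of the Caspase-8 knockdown itself may add to the spread over the listed probes and was not tested.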

How the results depend on the processing

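Scaling on the spike-ins, the common floor and the restriction to probes above the dark corner were chosen only after seeing the data, and the other alternatives were planned. Of 85 named differences recomputed 510 times, 0 changed direction, 463 moved by less than 1.5 times and 47 by more. Of the 47, 38 did so with spike-in scaling, 5 with the pseudocount and 4 with quantile normalization. The features were named for their large differences, so the 0 was largely set by that selection and is no test of robustness. Spike-in scaling turned the sign of 14 of the 18 family medians in each comparison with control. Signal over background limits the dim probes, since 3819 of the shared probes were not above the dark corner of the Caspase-8 shRNA array, against 1613 and 2025 on the control and c-Src shRNA arrays. No paired analysis was possible because the labels give no replicate numbers and each group had 1 array. The brightest probe per gene and gene means were not run, as no name was shared by more than 1 probe, and neither was normexp correction, as no background values were used here. The knocked-down genes and the gene lists have no value. Counts that moved by over 1.5 times follow, each with the count of probes higher or lower in the array named first, and the cause was not tested except where stated.

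Probes higher in Caspase-8 shRNA than in control shRNA, 4551 in the main setting, numbered 1625 above the dark corner, 1088 with the common floor, 1820 with mean signal at or above the 25th percentile and 899 at or above the median. These settings remove or level dim probes by construction. The same count was 1788 after quantile normalization, 1033 after cyclic loess, 2782 with spike-in scaling and 2625 at 4-fold. Lower probes, 986, numbered 1823 after quantile normalization, 2817 with spike-in scaling, 1753 at 1.5-fold and 145 at 4-fold. A changed fold size moves the counts by construction here and below.

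Probes higher in c-Src shRNA than in control shRNA, 737, numbered 331 after quantile normalization, 486 with median centring, 404 at or above the 25th percentile, 164 at or above the median, 387 with the pseudocount, 326 with spike-in scaling, 270 with the common floor, 1941 at 1.5-fold and 105 at 4-fold. Lower probes, 541, numbered 341, 330, 125, 180, 1331 and 179 under quantile normalization, the 25th percentile, the median filter, the pseudocount, spike-in scaling and the common floor, and 1467 at 1.5-fold and 63 at 4-fold. These main counts cover 13468 probes, while normalization, centring and the signal filters were run on the 11004 shared probes or a part of them, on which the main setting gave 614 higher and 435 lower. Against 614 and 435, the 486 with median centring, the 341 after quantile normalization and the 330 at the 25th percentile moved by less than 1.5 times.

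Probes higher in c-Src than in Caspase-8 shRNA, 1085, numbered 1869 after quantile normalization, 2112 with spike-in scaling, 1915 at 1.5-fold and 205 at 4-fold. Lower probes, 4520, numbered 1541 above the dark corner, 1090 with the common floor, 1210 after cyclic loess, 1798 and 906 with the filters at the 25th percentile and the median, 1979 after quantile normalization and 2676 at 4-fold.

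Probes higher in both knockdowns, 406, numbered 95 above the dark corner, 34 with the common floor, 99 after cyclic loess, 62 after quantile normalization, 196 and 32 with the 25th percentile and median filters, 146 with the pseudocount, 136 with spike-in scaling, 1091 at 1.5-fold and 48 at 4-fold. Probes lower in both, 46, numbered 123 after cyclic loess, 130 after quantile normalization, 30 with the median filter, 28 with the pseudocount, 339 with spike-in scaling, 259 at 1.5-fold and 5 at 4-fold.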

Other observations

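The tests of the shared control covariance and of the brightness of the SRP RNA features were chosen only after the results were seen, as were the 16-fold counts and the features named next, while the 4-fold test and the loess test were chosen before.

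A few probes without an RNA name differed most in a single line. CB_018008 had a signal of 34209 in the control line, 6537 in the c-Src shRNA line and 301 in the Caspase-8 shRNA line, so it was 56.3-fold lower in the last and 3.79-fold lower in the c-Src line. CB_028387 had signals of 29.3, 28.0 and 422 in the control, Caspase-8 and c-Src shRNA lines, and was 19.9-fold higher with c-Src shRNA. Among features named for small nuclear RNA, SNRNA_77_312 read 718, 117 and 507, and snRNA_50_320 read 56.5, 104 and 48.2, in the order control, Caspase-8 and c-Src, so members of this class differed in opposite directions in the Caspase-8 shRNA line.

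Features lower in both knockdown lines were weighed against error of the control array. Over all 6883 probes, the covariance lay below the simulated mean by a difference of -0.0343. The simulation took the whole observed spread as error, so it could not show whether such error was enough for the shared movement. For the 5 probes at least 4-fold lower in both, CB_029506, RefSeq_253_4942, ENCODE_2283_423, RNAz_2444_254 and RefSeq_3217_605, symmetric spot noise of the control array cannot be told apart from a real difference, as simulations without those probes gave up to 9. Of these, 3 were at least 16-fold lower in both, against at most 1 in those simulations, with 0 at least 16-fold higher, but with 1 control array a single bright artefact per spot remains open. A loss of these RNAs with the mesenchymal-like state may also explain them and was not tested. Each group was 1 line on 1 array, so the shRNA, the cell state and the line itself cannot be told apart.

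SRP RNA features had positive differences from control for 11 and 12 of 12 features in the Caspase-8 and c-Src shRNA arrays, of which 3 and 1 were at least 2-fold, and for 4 and 9 with spike-in scaling, where the medians were -0.18 and 0.13. The median in the Caspase-8 array was at the 64.8th percentile of matched sets, so it was not told apart from equally bright probes. Brightness may account for it, but a middling rank of 12 features does not show that it does. Removing the trend with brightness by cyclic loess left a median of -0.13 there, so the use of 1 scaling for all probes may account for it. In the c-Src array the median after loess was 0.18, at the 96.9th percentile, and a biological difference stays open and untested. The 12 features carry the name of 1 RNA and may not be independent of each other.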
